A study of Mus musculus with 6 samples.

How the data were processed

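RNA of sorted CD4+CD8+ double-positive thymocytes from mice carrying a Sox13 transgene and from wild-type littermates was measured on Affymetrix arrays in 2 experiments. Experiment 1 used the Mu11K A and B arrays, which carry different probe sets, and experiment 2 used the U74A version 2 array. Each array type was hybridised with 1 transgenic and 1 wild-type sample, giving 6 arrays in all and 3 per genotype. The A and B arrays of experiment 1 were counted as 1 replicate. Per the labels, the mice were 6 weeks old. The series text states that each sort pooled thymocytes of at least 2 mice, so no p-value here measures the spread between single mice.

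The deposited values are intensities on a linear scale, 1 per probe set. The series text names Microarray Analysis Software versions 4 and 5 for the study as a whole, and MAS5 is named in the submitters' processing notes. Which version made which array's values, and the scaling target, are not given in the sources used here. The Mu11K values included negative intensities, from 17.3% to 29.2% of the probe sets used on an array, and the U74A values had none. The 2% trimmed means of the deposited intensities were nearly equal within each pair, at 2476 and 2478 on Mu11K A, 2462 and 2462 on Mu11K B and 248.5 and 248.5 on U74A, with the transgenic array given before the wild type. The medians of the deposited intensities were 639.4 and 815 on Mu11K A, 396.6 and 545 on Mu11K B and 65.4 and 68 on U74A. No detection calls were used.

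AFFX control probe sets were left out, 55 on each Mu11K array and 66 on the U74A array, together with 21 other Mu11K A probe sets that had no wild-type value. Each array was scaled to a 2% trimmed mean of 500, intensities under a floor of 100 were set to 100, and log2 was taken. A fold against a sample at the floor is a lower bound and is written "at least". Between 46.9% and 57.4% of the probe sets of an array lay above the floor. The number of arrays limits the precision of every value.

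Genes were named from the platform annotation, with symbols checked against RefSeq genes of the GRCm38.p6 assembly, which changed 0 names. On Mu11K A, 5530 probe sets had 1 symbol, 197 had several and 781 had none. On Mu11K B the numbers were 2001, 27 and 4512, and on U74A 10833, 396 and 1193. Only probe sets with 1 symbol named a gene. Within an experiment, the log2 ratios of a gene's probe sets above the floor on at least 1 array were averaged. No coordinates were used.

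The test across experiments was limma (version 3.58.1, R 4.3.3), fitted to the log2 ratio of transgenic over wild type of each experiment, intercept against 0, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. It covered the 3237 genes measured in both experiments. The prior, a variance shared over genes, had 12.1 degrees of freedom. It therefore outweighs a gene's own spread between the 2 pairs of pooled samples in the limma SE and p-values. Within an array type no test was made, and probe sets with a difference of 2-fold or more were counted. Before the data were examined, the rule for naming genes and 20 gene lists from textbook knowledge were fixed. The lists were gamma-delta associated genes, the alpha-beta double-positive program, TCF/LEF and Wnt, T cell receptor response, mature single-positive, double-negative progenitor, cell cycle, cell death, Notch and bHLH factors, cytokine receptor signaling, interferon response, stress and heat shock, ribosome and translation, oxidative phosphorylation, glycolysis, B cell, myeloid, stroma and epithelium, erythroid and natural killer (NK) cell. The 19 lists with at least 5 tested genes entered limma's camera with a preset inter-gene correlation of 0.01. With this setting its p-values rest on the spread between genes, not on the spread between the 2 pairs. With an estimated correlation, an alternative, they rest on the 2 ratios, and a list can hardly pass. As a description of each experiment, a list's median log2 ratio was placed among the medians of 10000 random lists matched on level, not on gene length.

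The rule for naming genes takes Sox13, then 12 genes per direction, made up of those past the threshold and filled with genes above the floor on all arrays by the smaller of their absolute log2 ratios. It adds up to 5 genes per direction at the floor in 1 genotype in both experiments, up to 4 members of each list with the same sign in both, and the 5 probe sets per direction with the largest log2 ratio on each array type. Members of the gamma-delta and alpha-beta lists may be named whether or not they changed.

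The fit was tested on simulated ratios for the 3237 genes with the noise of each experiment, independent between genes, in 20 simulations. It called 25.4% of 2-fold, 96.1% of 4-fold, 99.8% of 8-fold and 100% of 16-fold changes, and 3.02% of its calls were unchanged genes. Camera called 100% of lists of 15 genes shifted by 0.7 log2 and 0.286% of unshifted ones. Each simulated change was equal in both experiments, and 200 genes changed in each simulation. The shares called depend on that number, since the adjusted threshold loosens as more genes change. In the data, near-equal changes of Cd7 (1.99-fold and 2.00-fold, adjusted p = 0.649, limma) and Usp18 (2.87-fold and 3.20-fold, 0.156) did not pass. The shares called may therefore not carry over to the data. The estimated inter-gene correlation in the data reached 0.333, in the double-negative progenitor list, so the false call rates may not carry over either. The alternatives were floors of 50 and 200, quantile, median and loess scaling, stricter and no filtering, the brightest probe set of a gene, an intensity trend in limma, an adjusted p of 0.1, an unpaired fit, thresholds of 1.5-fold and 3-fold, an estimated correlation, fry, and each experiment left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.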

Results

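Double-positive thymocytes carry both CD4 and CD8 and are the intermediate stage of alpha-beta T cell development. Sox13 is an HMG-box transcription factor linked to the gamma-delta T cell lineage. The series compared double-positive thymocytes of Sox13 transgenic mice with those of wild-type littermates, to find genes whose expression depends on Sox13. Each genotype had 3 arrays, namely Mu11K A and Mu11K B in experiment 1 and U74A in experiment 2. Values are scaled intensities, in which the trimmed mean of an array is 500 and the floor is 100. Of the probe sets used, 3494 of the transgenic and 3737 of the wild-type sample lay above the floor on Mu11K A, 3067 and 3359 on Mu11K B, and 6721 and 6844 on U74A.

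The transgene was read by 1 probe set in each experiment. In experiment 1 the Sox13 intensity was 5951 in the transgenic sample and below the floor in the wild type, a difference of at least 59.5-fold. In experiment 2 it was 3832 against 599.6, or 6.39-fold higher. With the wild type of experiment 1 taken at the floor, the mean log2 ratio was 4.29 ± 0.56 (limma SE, n = 2 experiments; adjusted p = 0.00543). The call was lost with a floor of 50 (adjusted p = 0.152, limma), without a filter on low values (0.846) and with the brightest probe set of each gene (0.0722). It was also lost in the unpaired fit, which called 0 genes. That fit pooled levels of different array types, so differences between array types entered its spread, and its 0 calls say little about Sox13. Over the paired alternatives the adjusted p ranged from 1.68e-06 to 0.846.

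Which genes had a mean log2 ratio other than 0 over the 2 experiments was asked over 3237 genes. The test does not require the experiments to agree. The transgenic sorted samples had higher levels of Sox13, of the Notch pathway regulator Dtx1, of the cysteine-rich protein gene Plac8 and of the globin genes Hba-a1 and Hbb-b2. These 5 genes passed the limma test, which does not tell which cells of a sample held the transcripts. Dtx1 rose at least 32.2-fold in experiment 1, from below the floor to 3221, and 6.59-fold in experiment 2, from 210.7 to 1388 (mean log2 ratio 3.86 ± 0.46, limma SE; adjusted p = 0.00428). Plac8 rose 8.63-fold, from 158.8 to 1370.0, and 4.53-fold, from 548.5 to 2483 (2.64 ± 0.36; adjusted p = 0.00605, limma). Hba-a1, an alpha-globin gene, rose 3.73-fold and 6.77-fold (2.33 ± 0.36; adjusted p = 0.0154, limma), although its 2 probe sets of experiment 1 differed, with log2 ratios of -0.03 and 3.83. Hbb-b2, a beta-globin gene, rose 8.22-fold and at least 2.91-fold (2.29 ± 0.40; adjusted p = 0.0399, limma). The means of Dtx1 and Hbb-b2 also take a wild-type sample at the floor.

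No gene was lower at this threshold, where limma gave 0 genes after adjustment and 127 at an unadjusted p under 0.05, against 81 higher and 162 expected by chance in all. The count of 5 higher genes depended on the processing. It was 0 with a floor of 50, 0 without a filter, 1 with the brightest probe set, 2 among genes above the floor on all arrays and 12 after quantile normalization, and 0 in the unpaired fit.

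**Figure D1:**
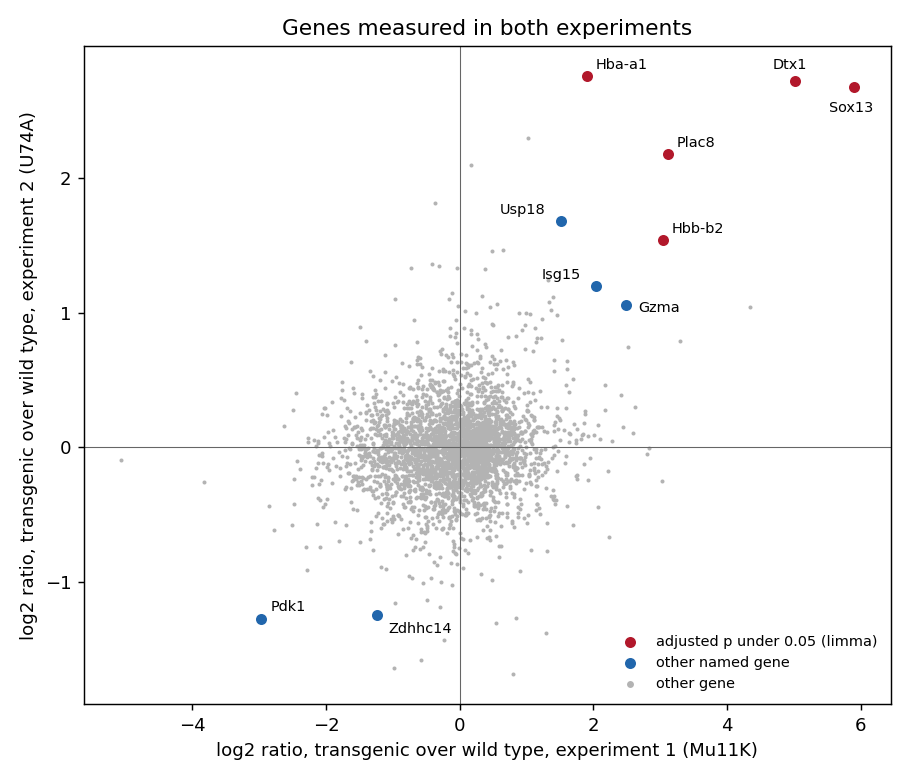
Log2 ratio of transgenic over wild type for 3237 genes, with experiment 1 on the horizontal and experiment 2 on the vertical axis, where red points passed the limma test and blue points are other named genes. Sox13 and Dtx1 lie farthest to the right, with log2 ratios of at least 5.90 and at least 5.01 in experiment 1.

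Beyond these genes, the genes above the floor on all arrays with the largest differences held by both experiments included Usp18, Isg15, Gzma, Ctss and H2-Aa, and none of them passed. Usp18, which removes ISG15 from proteins, was 2.87-fold and 3.20-fold higher in experiments 1 and 2 (adjusted p = 0.156, limma), and Isg15 itself was 4.10-fold and 2.29-fold higher (adjusted p = 0.181, limma). The granzyme gene Gzma was 5.60-fold and 2.08-fold higher (adjusted p = 0.181, limma). The cathepsin gene Ctss was 2.49-fold and 2.37-fold higher, the class II gene H2-Aa 2.53-fold and 2.11-fold, the transcription factor gene Irf8 2.07-fold and 1.99-fold, and Cd7 1.99-fold and 2.00-fold. Under other scalings Usp18 passed in limma, at adjusted p values of 0.012 (quantile), 0.0445 (median) and 0.0426 (loess), against 0.846 without a filter. Isg15 and Gzma passed under quantile and median scaling, at 0.0151 and 0.0445 for Isg15 and 0.0184 and 0.0432 for Gzma, against 0.846 without a filter. The fit without a filter held 5877 genes, with a median log2 ratio of 0 in both experiments, since many lay at the floor. Its shared value of 0.846 reflects that fit as a whole rather than a single gene.

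Among the lower transcripts, Pdk1, a kinase that inhibits pyruvate dehydrogenase, was 7.81-fold lower in experiment 1 (127.1 against 991.9) and 2.42-fold lower in experiment 2 (699.5 against 1689). Its mean log2 ratio of -2.12 did not pass (adjusted p = 0.0971, limma), but did with a floor of 200 and under quantile, median and loess scaling, at adjusted p values of 0.0452, 0.00538, 0.0134 and 0.0426, against 0.846 without a filter. The palmitoyltransferase gene Zdhhc14 was 2.34-fold and 2.37-fold lower, and Wdr78 4.84-fold and 1.88-fold lower (adjusted p = 0.294, with a range over the alternatives of 0.0458, after quantile normalization, to 0.848, with a floor of 50, limma). P4ha1, Serbp1, Lmo4, Synrg, Abca1, Vamp1, Smap2, Prep and Parg were also lower in both experiments, with mean log2 ratios from -1.52 for Abca1 to -0.73 for Prep, and did not pass.

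Some genes were at the floor in 1 genotype in both experiments, so that only bounds exist. S100a6, which encodes a calcium-binding protein, was at least 2.63-fold and at least 2.17-fold higher in the transgenic samples. Tha1, Gfra1, Rangrf and Myl10 were also above the floor in the transgenic samples alone. The carbonic anhydrase gene Car2 was at least 1.98-fold and at least 3.11-fold lower, and Pecam1 at least 2.15-fold and at least 1.87-fold lower. Chrnb1, Siae and Ktn1 were above the floor in the wild-type samples alone.

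A difference of 2-fold or more in the same direction in both experiments was found for 14 higher and 2 lower genes, where 1.81 and 1.68 are expected for independent experiments, and 1 gene differed 2-fold in opposite directions. The lower genes were Pdk1 and Zdhhc14. The higher genes included Pdlim4, at least 20.3-fold and 2.06-fold, and the T cell receptor gamma segment Trgv1, at least 2.02-fold and at least 4.92-fold, both named after their values were seen. Neither passed in limma (adjusted p = 0.156 and 0.228), but Pdlim4 passed under quantile and median scaling and Trgv1 under quantile scaling. In experiment 1, 183 genes were 2-fold higher and 389 lower, and in experiment 2, 32 and 14.

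The experiments shared little of their variation across genes. Pearson's correlation of their log2 ratios was 0.178 (95% interval 0.145 to 0.212) and Spearman's was 0.109, a description across genes, which are not independent replicates. The sign was the same for 54.3% of genes. The SD of the log2 ratios was 0.78 in experiment 1 and 0.33 in experiment 2.

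**Figure D2:**
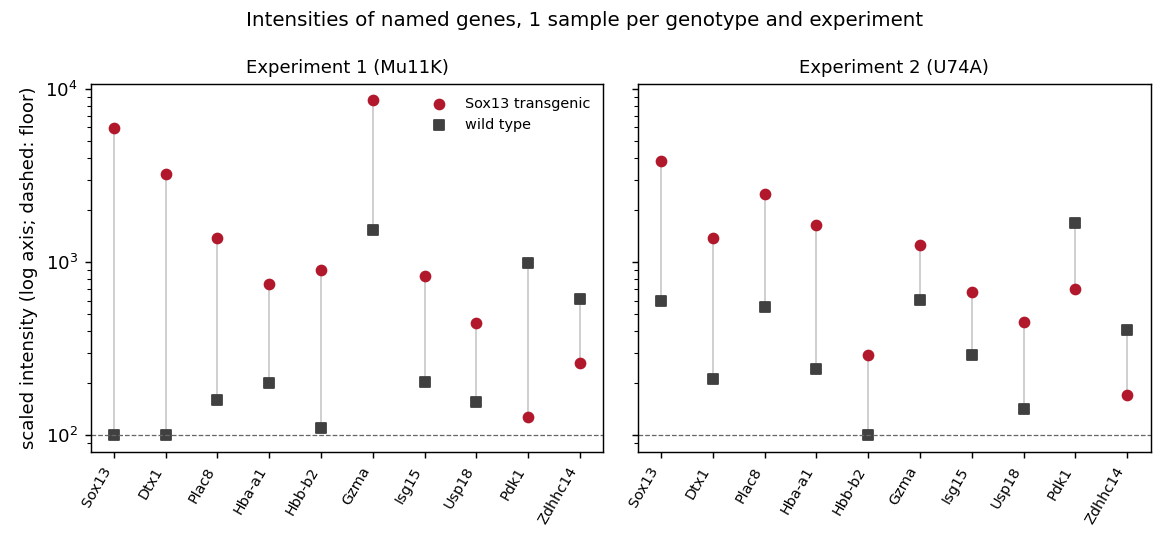
Scaled intensity on a log axis of 10 named genes in each experiment, with 1 transgenic (red circle) and 1 wild-type sample (black square) and the floor as a dashed line. Sox13 reached 5951 and 3832 in the transgenic samples, and Pdk1 was lower in the transgenic sample of both experiments.

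Gamma-delta associated genes were higher as a group, with medians over all measured members of 0.30 in experiment 1 and 0.11 in experiment 2. Of the 11 tested, 7 were higher and 2 lower in both experiments, with a mean log2 ratio of 0.82 (camera adjusted p = 6.13e-05, and adjusted p = 0.762 with an estimated correlation). The list holds the transgene itself, and without Sox13, a choice made after seeing the data, the mean was 0.47 (camera adjusted p = 0.00433). Among genes above the floor on all arrays, which leaves out Sox13, the mean was 0.28 (camera adjusted p = 0.170), and without a filter it was 0.34 (0.361), where the alternatives ranged from 1.81e-05 to 0.762. Only Sox13 passed over all genes, against 4 genes when adjusted over the list alone, namely Sox13, Gzma, S100a6 and the Src-family kinase gene Blk. Blk was at least 2.58-fold and at least 2.03-fold higher, where its 2 probe sets of experiment 2 differed, with log2 ratios of at least 0.20 and at least 1.85. Sox4 had log2 ratios of 0.64 and 0.11, Id3 of 0.22 and -0.41, Egr1 of -0.11 and -0.42, and Il7r, measured in experiment 2 and at the floor in the wild type, of at least 0.04.

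The alpha-beta double-positive program did not pass as a group in camera. As a description, its medians over all measured members, -0.11 in experiment 1 and -0.05 in experiment 2, lay at percentiles of 0.82 and 10.6 of random lists. Those random lists were not matched on gene length. Of 35 tested genes, 3 were higher and 13 lower in both experiments, with a mean log2 ratio of -0.15 (camera adjusted p = 0.468), 0 genes passed over all genes and 0 when adjusted over the list alone. The coreceptor gene Cd4 had log2 ratios of -0.00 and -0.37, Cd8a of -0.11 and -0.18, and the recombinase genes Rag1 of -0.56 and 0.30 and Rag2 of -2.02 and 0.08. The 2 Rag1 probe sets of experiment 2 differed, at -0.12 in the brighter and at least 0.73 in the other. The costimulatory receptor gene Cd28 had log2 ratios of -2.86 and -0.43, Tcf12 of -1.43 and -0.31, and Satb1 of -0.55 and -0.34. Ptcra, which encodes the pre-T cell receptor alpha chain, had 1.61 and 0.58.

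Of 6 tested genes of double-negative progenitors, the stage before the double-positive cell, 4 were higher and 0 lower in both experiments, with a mean log2 ratio of 1.27 (camera adjusted p = 3.11e-06, and adjusted p = 0.762 with an estimated correlation). Those higher in both were Dtx1, Notch1 (2.63 and 0.30), Notch3 (1.42 and 0.65) and Ptcra, although the brighter of the 2 Notch1 probe sets of experiment 2 was at -0.00 and the other at 0.60. In this list 1 gene passed over all genes against 4 when adjusted over the list alone. Over all measured members of the list the median was 0.32 in experiment 1, with 6 of 9 higher, and 0.02 in experiment 2, with 6 of 12 higher. Without Dtx1, Notch1, Notch3 and Ptcra, a choice made after seeing the data, the medians were -0.21 and -0.23. Without a filter the list's call was lost (mean 0.32, camera adjusted p = 0.741), where the alternatives ranged from 3.45e-07 to 0.762. Kit and Cd34, measured in experiment 1 and under 200 in both genotypes, had log2 ratios of -0.21 or lower and of -0.74. The Notch and bHLH list of 12 genes, which shares Dtx1, Notch1 and Notch3, did not pass (mean 0.34, median -0.09, camera adjusted p = 0.262), with 1 gene past the test over all genes and 3 when adjusted over the list alone. Its 14 members of experiment 1 had a median of 0.21, with 8 higher and 6 lower. The 14 of experiment 2 had a median of -0.27, with 3 higher and 11 lower.

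Interferon response genes were higher, 10 of 17 in both experiments and 2 lower, with a mean log2 ratio of 0.39 (camera adjusted p = 3.94e-04, and adjusted p = 0.762 with an estimated correlation). Irf9 had log2 ratios of at least 0.94 and of 0.87. Igtp (-0.74 and -0.55) was 1 of the 2 lower in both, and Gbp2 (-1.26 and 0.14) 1 of the 5 with opposite signs. The wild-type intensities of Irf7 and Irf8 in experiment 2, 100.5 and 106.8, lay close to the floor. In this list 0 genes passed over all genes and 4 when adjusted over the list alone, namely Usp18, Isg15, Irf7 and Irf8. Genes of mature single-positive thymocytes had a mean log2 ratio of 0.40 over 14 genes, 8 higher and 5 lower in both (camera adjusted p = 0.00433, and adjusted p = 0.762 with an estimated correlation). The class I genes H2-D1 (1.70 and 0.50) and H2-K1 (1.63 and 0.41) and the cytokine signaling inhibitor gene Socs3 (3.29 and 0.79) were higher, and Emb was lower (-0.99 and -0.53). In the mature list 0 genes passed over all genes and 1, Socs3, when adjusted over the list alone. Under quantile and median scaling Socs3 also passed over all genes in limma. The call of the mature list was also lost without a filter (mean 0.30, camera adjusted p = 0.0711), where the alternatives ranged from 8.32e-04 to 0.762.

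Several lists held markers of cells outside the sort gate, and their results differed. B cell genes were higher, 8 of 11 in both experiments and 0 lower in both, with a mean log2 ratio of 0.52 (camera adjusted p = 6.13e-05, and adjusted p = 0.762 with an estimated correlation). The class II genes and invariant chain led this list, with H2-Aa at 1.34 and 1.08, Cd74 at 1.23 and 0.95, H2-Ab1 at 1.59 and 0.46 and H2-Eb1 at 0.56 and 0.62. The 2 H2-Eb1 probe sets of experiment 1 had opposite signs, at -0.25 and 1.37. In the B cell list 0 genes passed over all genes against 2 when adjusted over the list alone. Myeloid genes had a mean log2 ratio of 0.29 over 10 genes (camera adjusted p = 0.0493, and adjusted p = 0.762 with an estimated correlation), with 2 higher and 1 lower in both, 0 genes past the test over all genes and 1, Ctss, when adjusted over the list alone. Their median was -0.22 in experiment 1, with 4 of 13 higher, and 0.59 in experiment 2, with 15 of 19 higher. The myeloid call was also lost with a floor of 200 (camera adjusted p = 0.112), without a filter (0.361) and, in choices made after seeing the data, without the largest member (0.221) and with members of 1 list only (0.0561), where the alternatives ranged from 0.0087 to 0.771. The erythroid list did not pass (camera adjusted p = 0.443). Its mean log2 ratio was 0.29 and its median -0.29 over 7 genes, with the globin genes higher and Car2 and Gata1 lower, and 2 genes passed over all genes against 3 when adjusted over the list alone. The stroma and epithelium list did not pass either (5 genes, mean -0.11, camera adjusted p = 0.680), with 0 genes past either test. Of the NK list only Gzma was measured in both experiments, and it did not pass over all genes (0). It passed over the list alone (1 gene), but adjusting over 1 gene leaves its p-value as it was. That pass therefore says nothing about the list.

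Cell cycle genes had medians of opposite sign in the experiments, a difference that was not tested. Their median log2 ratio was -0.16 in experiment 1, with 18 of 46 higher, and 0.35 in experiment 2, with 48 of 52 higher, at percentiles of 1.49 and 100 of random lists. Within the list, Spearman's rho across genes between genomic length and log2 ratio was -0.403 in experiment 1 and 0.322 in experiment 2, against -0.326 and -0.0753 over all genes, which are not independent replicates. Their mean was 0.03 over 44 genes (camera adjusted p = 0.240). Tk1, Plk1, Mcm7 and Lig1 were higher in both, at 0.41 and 0.48, 0.38 and 0.52, 0.64 and 0.37, and 0.35 and 0.52. The remaining lists did not pass in camera. Their adjusted p and mean log2 ratio were 0.680 and 0.00 for TCF/LEF and Wnt, 0.443 and 0.04 for T cell receptor response, 0.896 and -0.07 for cell death, 0.680 and 0.05 for cytokine receptor signaling and 0.523 and -0.16 for stress and heat shock. For ribosome and translation they were 0.434 and 0.06, for oxidative phosphorylation 0.128 and 0.12, and for glycolysis 0.128 and 0.14. Cell death and cytokine receptor signaling had medians of the other sign, 0.01 and -0.04. Oxidative phosphorylation passed without a filter (camera adjusted p = 1.29e-05), a setting in which many of the other genes had ratios of 0. Glycolysis passed without Pdk1, a choice made after seeing the data (mean 0.43, camera adjusted p = 0.00451). These are the lowest of their alternatives, which reached 0.762 and 0.771. In cell cycle and in these lists 0 genes passed over all genes, and when adjusted over the list alone 1 gene passed for glycolysis (Pdk1), 1 for cytokine receptor signaling (Socs3) and 0 for each of the others. In all, 6 of 19 lists passed, 0 with an estimated correlation and 0 by fry. These 2 alternatives rest on 2 ratios, which leave little power over 19 lists. The B cell list lost its call with an estimated correlation of -0.018 (camera p = 0.135), so such a loss need not come from correlated genes.

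**Figure D3:**
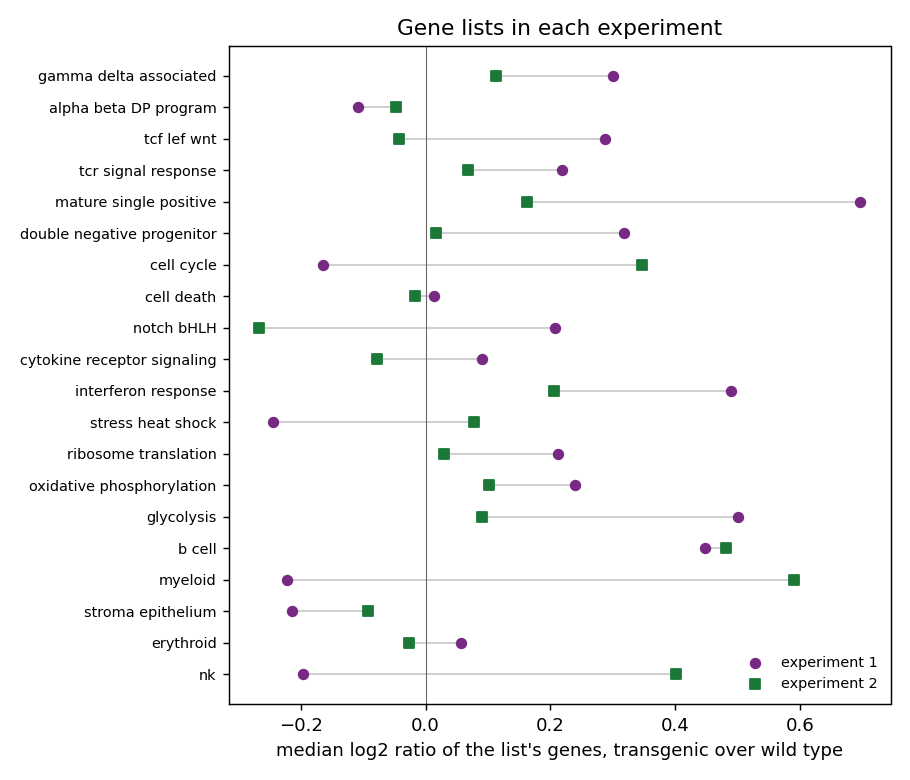
Median log2 ratio of transgenic over wild type of each of the 20 gene lists, over all members measured in experiment 1 (purple circle) and in experiment 2 (green square). The B cell list lies at 0.45 and 0.48. The myeloid, cell cycle, TCF/LEF and Wnt, and Notch and bHLH lists lie on opposite sides of 0 in the experiments. So do the cytokine receptor signaling, stress and heat shock, cell death, erythroid and NK lists. The NK medians rest on 3 and 2 genes.

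On single array types, without replicates, the largest differences among probe sets above the floor on both arrays included Socs3, Notch1, Ctse, Ctsl and Anp32a. The counts also take in probe sets above the floor in 1 genotype alone, such as Sox13 and Dtx1 on Mu11K A, and the genes listed do not. On Mu11K A, 177 probe sets were 2-fold higher and 455 lower of 3882, with the listed genes being Socs3 (9.78-fold), Plac8, Rfng, Cnn3 and Notch1 among the higher and Pdk1, Cd28, Ckap5, Top2a and Upf2 among the lower. On Mu11K B, 220 were higher and 498 lower of 3577. The listed higher genes were Hba-a1 (14.2-fold), Hbb-b2, Notch1 (6.90-fold), Gzma and Cbx1, and the lower ones Ctse (33.5-fold), Ctsl (14.6-fold and 13.7-fold in its 2 probe sets), Chd1 and Mki67 (5.63-fold). On U74A, 69 were higher and 40 lower of 7109, with Anp32a (10.7-fold), Hba-a1, Dtx1, Sox13 and Plac8 among the higher and H1f10 (3.22-fold), Tcf25, Rmc1, Ly6d and Bmyc among the lower. Other probe sets differed from those listed for Cbx1, at a log2 ratio of -0.84 in experiment 1, and for Anp32a, at 0.21 on U74A. Several listed genes had the other sign in the other experiment. In experiment 2 the log2 ratio was -0.25 for Rfng, -0.05 for Cnn3, 0.07 for Ckap5, 0.40 for Top2a, 0.16 for Chd1 and 0.28 for Mki67, and in experiment 1 it was -0.37 for Anp32a, 0.80 for H1f10 and 1.30 for Ly6d. The cathepsin genes Ctse and Ctsl differed on U74A by 1.19-fold or less in each probe set. Under quantile scaling Ctse still passed in limma, which tests the mean of the experiments and not their agreement. After quantile normalization the counts were 244 higher and 322 lower on Mu11K A and 314 and 360 on Mu11K B.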

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

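The limits come from 2 pairs of samples, of which experiment 1 has the wider spread, and from a floor that decides how far a low gene can move. The list alternatives that leave out the transgene, the largest member or shared members were chosen after seeing the data, and the cause of a change was not tested unless given. Quantile normalization moved the median log2 ratio of all genes in experiment 1 from -0.05 to 0.06.

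The count of 5 higher genes became 0 with a floor of 50, 0 without a filter, 1 with the brightest probe set and 2 among genes above the floor on all arrays, which leaves fewer genes tested. It was 0 with no replicate block, the unpaired fit whose spread takes in the differences between array types. It became 12 under quantile and 10 under median scaling. All 5 genes were among the calls under quantile, median and loess scaling, and 4 of them with a floor of 200. The 0 lower genes became 1 with a floor of 200, 3 under quantile, 1 under median and 1 under loess scaling, 1 with an intensity trend and 1 at an adjusted p of 0.1. Each of the 5 genes was 2-fold higher in either experiment alone. The wild-type intensities of Dtx1, Hba-a1, Hbb-b2, Usp18, Isg15 and Ctss lay under 3 times the floor in both experiments. Those of Sox13 and Plac8 did so in experiment 1. Sox13 kept its direction, with mean log2 ratios of 4.79, 4.29 and 4.29 and no call with a floor of 50, no filter and the brightest probe set. With an experiment left out its value was 2.68 to 5.90, of which the upper is a lower bound, since that wild-type sample was at the floor.

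The 14 genes 2-fold higher in both became 7 among genes above the floor on all arrays, 41 at 1.5-fold and 4 at 3-fold. The 2 lower became 5 with a floor of 50, 29 at 1.5-fold and 0 at 3-fold. With 1 experiment left out, 32 to 183 were higher and 14 to 389 lower. The Pearson correlation was 0.139 with a floor of 50 and 0.138 among genes above the floor on all arrays.

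Probe sets 2-fold higher and lower on U74A became 156 and 133 with a floor of 50, 34 and 13 with a floor of 200, and 44 and 26 when above the floor on both arrays. With a floor of 200, 290 were lower on Mu11K A and 307 on Mu11K B. At 1.5-fold, higher and lower counts were 463 and 938 on Mu11K A, 512 and 983 on Mu11K B and 293 and 256 on U74A. At 3-fold they were 51 and 110, 77 and 162, and 16 and 4. Under loess the Mu11K counts were 230 and 334 on A and 292 and 367 on B.

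The 6 lists past the threshold became 3 without a filter, of which interferon response and B cell were among the 6 and oxidative phosphorylation was not, 0 with an estimated correlation and 0 by fry. The gamma-delta list lost its call among genes above the floor on all arrays (mean log2 ratio 0.28), without a filter (0.34), with an estimated correlation (0.82) and by fry (0.82). With 2 ratios, an estimated correlation and fry leave little power, so losses under them neither uphold nor refute a call. The myeloid list turned negative without experiment 2, at -0.079. The alpha-beta list was negative in every alternative run and was called in none of those that have a test. Among single genes and lists, 515 values were labelled unchanged, 28 lost a call, 14 gained one and 1 called value turned. Among the counts and main values 109 stayed, 48 moved and 7 lost a call. A gene or list without a call was labelled unchanged if it stayed uncalled, whatever its sign. With an experiment left out there is no test, and a gene or list could change its label only if it was called and turned.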

Other observations

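The tests of gene length and of loess scaling were planned before their results were seen, and all other tests given here were chosen after the values they use. Several T cell receptor gamma probe sets were higher in the transgenic samples on Mu11K A and on U74A, and were chosen after their values were seen. Trgv1 was higher in its 2 probe sets of Mu11K A, with log2 ratios of at least 0.45 and of 1.58, and at least 4.92-fold higher on U74A. Trgv4 was 4.29-fold higher on U74A, 908.7 against 212.1, and on Mu11K A had a log2 ratio of 0.17 in 1 probe set and was below the floor in both genotypes in another. The 3 probe sets that match several gamma segments were 3.27-fold and 6.06-fold higher on Mu11K A and 4.17-fold higher on U74A. Alpha and beta segments had log2 ratios from -0.90 (Trav9d-3, Mu11K A) to 0.18 (Trav19, U74A). These are values of single arrays. Over both experiments Trgv1 did not pass in limma (mean log2 ratio 1.66, adjusted p = 0.228), but it did after quantile normalization. No test is given here for the other segments.

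More Mu11K probe sets were 2-fold lower than higher, 953 against 397. The genes 2-fold lower in experiment 1 had a median log2 ratio of -0.063 in experiment 2 (median absolute deviation 0.25), and 59.9% of them were lower there against 53.4% of all genes, so a genotype effect on these genes, in both experiments or in experiment 1 alone, stays open. Longer genes had lower ratios in experiment 1 (Spearman's rho across genes -0.326, against -0.0753 in experiment 2), which is consistent with a loss of signal from long genes in that transgenic sample, although genomic length (GRCm38.p6) is not transcript length. Loess left 701 lower and 522 higher probe sets, a ratio of 1.34, so a level-dependent scaling difference may account for part of the excess. The 3' to 5' ratios on Mu11K B went both ways, with actin at 1.08 in transgenic and 1.32 in wild-type cells and Gapdh at 1.18 and 0.870.

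Globin and B cell transcripts, and myeloid ones in experiment 2, were higher although the cells were sorted by flow cytometry for CD4 and CD8, a gate that would remove other cells. The B cell list had median log2 ratios of 0.447 and 0.48, which some B cells or their RNA in the transgenic samples could give. In the wild type, 4 of its 12 members in experiment 1 and 9 of 15 in experiment 2 lay near the floor, which here means under 3 times the floor. Its class II genes, led by Cd74 (4243 against 1808 in experiment 1), also mark other antigen-presenting cells, and Cd79b was at 0.58 and -0.23. Myeloid genes had a median of 0.590 in experiment 2, where 16 of 19 lay near the floor and Lyz2 was at least 1.35, so myeloid cells may have contributed there. In experiment 1 that median was -0.222, with Lyz2 at -0.32 and Ctss at 1.32, and -0.06 under quantile and loess scaling with a wider spread, which leaves a contribution open. Erythroid genes other than globins had a median of -0.365, but 4 of the 5 lay near the floor, so nucleated erythroid cells cannot be told apart from a change in globin transcripts alone.

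Dtx1, Notch3, Ptcra, Gzma and gamma segments were higher, which a transgene effect in double-positive cells or a share of other thymocytes could give. The double-negative markers other than Dtx1, Notch1, Notch3 and Ptcra had medians of -0.211 and -0.23, but 3 of 5 and 5 of 8 lay near the floor, so a share of double-negative cells stays open. The gamma-delta list without the transgene had medians of 0.26 and 0.0748, with members on both sides of 0, so gamma-delta cells also stay open. Il2ra, a double-negative marker, was below the floor in all samples.

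With the genotype labels of experiment 2 turned, limma called 1 gene against the real 5. Only 2 such splits exist, and 1 of the 2, the real one, gave 5 or more, which is too few splits for a share under 0.05.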
